A study of Oryza sativa with 35 samples.

How the data were processed

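RNA from rice inflorescence meristems of Koshihikari and NIL-Gn1 was measured in 35 libraries by CEL-Seq2. Per the labels, growth chambers were held at 70% humidity, with days of 10 h (27 °C, 100 µmol m-2 s-1) and nights of 14 h (25 °C), RNA was extracted with a plant kit, and 100 pg of RNA per library was amplified with 11 to 15 PCR cycles. The authors' deposited table holds raw UMI counts, with no normalization, for 55801 loci named by MSU locus identifiers, of which 24425 had at least 1 UMI. The authors name Bowtie2 and Subread; their roles, the genome build and the annotation were not given in the sources used here. The values were checked to be whole and non-negative, and every column mapped to a sample. Libraries were grouped by line and tissue code into 8 groups, with 5, 5, 3 and 3 Koshihikari libraries and 8, 8, 1 and 2 NIL-Gn1 libraries at R1, R2, R4 and R5.

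Totals were 76743 to 375071 UMIs per library, so that 3 counts, taken as the limit that a count of 0 allows, equal 8.00 to 39.1 CPM. Levels are CPM over the tested loci with TMM factors, given as mean ± SD, and these limits use the raw totals. Counting intervals are 95% exact intervals of the ratio of 2 counts given their totals. Such intervals and limits cover counting error only.

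Counts were fitted in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr, robust quasi-likelihood F-test), with 1 coefficient for each of the 8 groups and all 35 libraries. The filter kept 7406 loci holding 86.7% of UMIs. The common dispersion was 0.0444, a biological coefficient of variation of 21.1%. P-values were adjusted by the Benjamini-Hochberg method over the tested loci within each comparison, and loci with an adjusted p under 0.05 were called. The SE of a log2 fold change was its size divided by the square root of F. All adjusted p-values of single loci are from this fit unless another tool is named. The comparisons of lines at R1, R2, R4 and R5, of R2 with R1 in each line, of R4 with R2 and R5 with R4 in Koshihikari and of R5 with R2 in NIL-Gn1, and the interaction of line with R2 against R1, were chosen before the data were examined, as were the gene lists, the list tests, the rule for named genes and the alternative settings. The contrasts of R4 and R5 together against R1 and R2 together, their interaction with line, and the line difference over R1 and R2 were chosen after the data were seen.

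Gene lists held 116 genes in 11 groups. Their symbols were compared with the RefSeq gene table by chromosome and gene order: 79 had the same chromosome and order and 1 symbol had several entries. The 4 placed on another chromosome (RCN1, OsIDS1, OsBOP1 and HSP90) were left out, as was OsCKX6, which had no entry in the count table. The symbols of 32 genes were not in that table and rest on the list alone, among them OsGA20ox1, OsGA2ox1, DST, DEP1, SNB, OsFD1, PsbO and HSP70. This left 111 genes. Lists with 6 or more tested genes were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry. Named genes were OsCKX2, up to 14 list members with the smallest p among those called, and the called loci with the smallest p and a log2 fold change of at least 1 in size. That last part of the rule asked for loci with a symbol or product name; as no table used here pairs the locus names with product names, at most 2 higher and 2 lower loci per comparison are given by identifier. OsCKX2 was tested by exact permutation of log2(CPM + 1), two-sided, in R, and counting intervals were computed with scipy 1.17.1. Placement of calls was tested by Fisher's exact test, two-sided. The planned windows in bases could not be placed without coordinates and were turned into numbers of loci after the data were seen.

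On simulated counts with these group sizes and depths, 41 of 100 loci changed 2-fold and 87 of 100 changed 4-fold were recovered for R1 between lines, 43 and 86 for R2, 4 and 47 for R5, and 3 and 33 for R4. Within lines 10 and 64 were recovered for R4 against R2 in Koshihikari and 16 and 60 for R5 against R2 in NIL-Gn1. Of 10 shifted lists camera called 10, and of 90 unchanged lists 0. All loci of a shifted list were raised 2-fold or 4-fold, and loci were simulated independently. This therefore says little on the real lists, whose estimated correlations were 0.0569 to 0.35. No pair of libraries in a group was a duplicate: over 83 pairs the chi-square per degree of freedom was at least 1.44.

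Alternatives were RLE and upper quartile normalization, no filter and a filter at a mean of 10 counts, DESeq2 1.42.0, limma-voom with sample quality weights, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Contrasts that use R4 of NIL-Gn1 could not be fitted without its only library. After the data were seen Koshihikari R2 reduced to replicates 2 and 3 was added. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.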

Results

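Inflorescence meristems of rice, the growing tips that lay down the branches and spikelets of the panicle, were profiled by CEL-Seq2, a 3′ RNA-seq method that counts molecules by unique molecular identifiers (UMIs). The 35 libraries came from Koshihikari, a japonica cultivar (16 libraries), and from NIL-Gn1 (19 libraries). By its name, NIL-Gn1 is a near-isogenic line at Gn1, a grain number locus whose gene Gn1a encodes the cytokinin oxidase OsCKX2. The labels do not say which allele it carries, and they do not define the tissue codes R1, R2, R4 and R5. Koshihikari had 5 libraries at R1, 5 at R2, 3 at R4 and 3 at R5, and NIL-Gn1 had 8, 8, 1 and 2. Totals ran from 76743 to 375071 UMIs per library (median 133163), and 12495 to 17630 loci were detected per library. The median total was 109532 UMIs in Koshihikari and 186188 in NIL-Gn1. A count of 0 in a library allowed a level of up to 8.00 CPM in the deepest library and 39.1 CPM in the shallowest. The labels do not say that the libraries of a group came from separate plants, so the p-values measure the spread between these libraries, which may be technical.

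The first principal component of log2 CPM held 14.5% of the variance and set R4 and R5 apart from R1 and R2 in both lines. Koshihikari libraries scored -11.0 ± 1.69 (SD, n = 5) at R1, -10.1 ± 2.44 (n = 5) at R2, 34.2 ± 1.91 (n = 3) at R4 and 40.2 ± 4.50 (n = 3) at R5. NIL-Gn1 libraries scored -11.5 ± 2.69 (n = 8) at R1, -10.0 ± 5.69 (n = 8) at R2, 16.2 in the single R4 library and 19.1 ± 6.30 (n = 2) at R5. On the second component (6.33% of the variance) Koshihikari R2 replicate 1 stood at -58.8, while the other 34 libraries lay between -14.7 and 14.3. On the fourth component (4.54%) Koshihikari R2 replicates 4 and 5 stood at 36.6 and 33.4, with the rest at 20.1 or below.

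OsCKX2 (LOC_Os01g10110), the cytokinin oxidase at Gn1, was near the limit of detection. It had 3 UMIs in the 35 libraries, 1 each in Koshihikari R1, Koshihikari R2 and NIL-Gn1 R2, where 3 counts over all 35 libraries equal 0.539 CPM. An exact two-sided permutation test of log2(CPM + 1) over the 1287 assignments of 13 libraries gave p = 0.385 at R1 and p = 1 at R2. With so few libraries holding a UMI, this test could not have given a p under 0.05 at R1 or R2. A cultivar difference in OsCKX2 was not detectable at this depth, and the gene could not be used to check the line labels. Other measured members of the cytokinin oxidase list were OsCKX3 and OsCKX11, and neither was called between the cultivars at R1, R2, R4 or R5. The florigen gene Hd3a and the spikelet regulator FZP had 0 UMIs in all 35 libraries, which allows up to 0.539 CPM over the series. Within single groups at R4 and R5, which hold fewer UMIs, it allows up to 8.00 CPM (Koshihikari R5) to 10.8 CPM (NIL-Gn1 R5).

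The cultivars were compared first in R1 tissue. DST (LOC_Os03g57240), a zinc finger transcription factor known to activate OsCKX2, was 2.11-fold higher in NIL-Gn1, at 282 ± 32.9 CPM (SD, n = 8) against 130 ± 41.7 CPM (n = 5) in Koshihikari (log2 fold change 1.08, SE 0.212, adjusted p = 0.00087). The ranges of the groups did not overlap, with NIL-Gn1 at 243 to 343 CPM and Koshihikari at 65.4 to 180 CPM. OsMADS18 (LOC_Os07g41370), a MADS-box gene of the floral transition, was 1.63-fold lower in NIL-Gn1, at 450 ± 78.3 CPM against 718 ± 191 CPM (log2 fold change -0.70, SE 0.158, adjusted p = 0.00947). Without Koshihikari R1 replicate 4 the OsMADS18 call was lost (-0.58, adjusted p = 0.108). In total 50 of 7406 loci were called, 14 higher and 36 lower in NIL-Gn1. The strongest calls without a gene name were LOC_Os12g39970 (log2 fold change 2.79, SE 0.252, adjusted p = 9.06e-16) and LOC_Os12g34062 (1.71, SE 0.307, 0.000144) among the higher loci. Among the lower loci they were LOC_Os01g03020 (-3.43, SE 0.333, 7.83e-15) and LOC_Os01g10140 (-1.89, SE 0.257, 5.03e-08).

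By gene group at R1, 1 of the 10 measured branch and spikelet regulators was higher in NIL-Gn1 (DST) and 9 were not called. Of the 7 measured florigen and floral transition genes 1 was lower (OsMADS18) and 6 were not called. Adjusted over the list alone, RFL, the rice LEAFY homologue, also passed among the branch regulators (log2 fold change -0.67, SE 0.224, adjusted p = 0.156 over all loci), and OsGA20ox1 passed among the 3 gibberellin genes (-0.56, SE 0.202, 0.228 over all loci). None of the 8 meristem maintenance genes, the 6 cell division genes, the 4 photosynthesis markers, the 3 lateral organ markers or the 2 heat shock genes was called at R1, over all loci or adjusted over the list alone. limma-voom called 124 loci and DESeq2 42.

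In R2 tissue 1 list gene was called between lines. OsGA20ox1 (LOC_Os03g63970), a gibberellin 20-oxidase of a late step of that pathway, was 2.14-fold lower in NIL-Gn1, at 171 ± 41.9 CPM (SD, n = 8) against 364 ± 110 CPM (n = 5; log2 fold change -1.10, SE 0.207, adjusted p = 0.000739). The ranges overlapped through Koshihikari R2 replicate 5, since Koshihikari ran from 169 to 425 CPM and NIL-Gn1 from 132 to 256 CPM. DST, called at R1, was at 204 ± 62.2 CPM in NIL-Gn1 and 202 ± 20.3 CPM in Koshihikari at R2 (log2 fold change 0.01, SE 0.215, adjusted p = 0.992). LOC_Os01g08860 had 0 UMIs in the 8 NIL-Gn1 libraries against 28 UMIs in the 5 Koshihikari libraries, at least 18.1-fold lower by the 95% counting interval (23.8-fold against a floor of 3 counts over the NIL-Gn1 group; adjusted p = 1.06e-06). LOC_Os12g39970 was again higher (log2 fold change 3.21, SE 0.288, adjusted p = 7.1e-16) and LOC_Os01g03020 again lower (-3.59, SE 0.358, 4.06e-14). LOC_Os02g39820 was higher (1.98, SE 0.502, 0.0298) but lost its call in 10 of 21 fits. Among these were the fits without Koshihikari R2 replicate 1 (adjusted p = 0.0674), 2 (0.0562), 3 (0.119) or 5 (0.0798) and without NIL-Gn1 R2 replicate 7 (0.0766) or 9 (0.0560). In total 37 loci were called, 5 higher and 32 lower. Without Koshihikari R2 replicate 1 the count was 16, and limma-voom called 24.

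Of the 3 measured gibberellin genes 1 was lower at R2 and 2 were not called, both over all loci and adjusted over the list alone. Members of the other lists were not called at R2, among them 10 branch and spikelet regulators, 8 meristem maintenance genes and 7 floral transition genes. The calls of R1 and R2, which share no libraries, had 9 lower loci in common where independent lists of 36 and 32 loci would share 0.156, and 1 higher locus where 0.00945 would be shared. These and later expected numbers take every tested locus as equally likely to be called, while all calls come from 1 shared fit. How much overlap that alone would give was not tested.

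Averaged over R1 and R2, a contrast chosen after the data were seen, NIL-Gn1 had lower OsGA20ox1 (log2 fold change -0.83, SE 0.144, adjusted p = 4.07e-05), lower OsMADS18 (-0.54, SE 0.113, 0.00149) and higher DST (0.54, SE 0.151, 0.0274). The OsGA20ox1 and OsMADS18 calls were kept in every setting tried, and the DST call was lost in 7 of 36 fits, among them without Koshihikari R1 replicate 2 (0.47, adjusted p = 0.0854), Koshihikari R1 replicate 4 (0.0520), Koshihikari R2 replicate 3 (0.0563) or NIL-Gn1 R2 replicate 7 (0.0518). In total 172 loci were called, 45 higher and 127 lower in NIL-Gn1. In each of these lists the remaining measured members, 9 branch regulators, 6 floral transition genes and 2 gibberellin genes, were not called.

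The calls were also placed along chromosome 1 by the order of the locus names, since the deposited table holds no coordinates and the build was not given in the sources used here. In a window of 744 loci on each side of OsCKX2, from LOC_Os01g02240 to LOC_Os01g18690, 8 of the 50 R1 calls fell among 268 tested loci (odds ratio 5.20, Fisher's exact two-sided p = 0.000379). At R2 it was 10 of 37 calls (odds ratio 10.2, exact p = 4.78e-07), and in a window of 297 loci on each side 2 calls (odds ratio 3.39, exact p = 0.127). Over R1 and R2 together 21 of 172 calls lay there, 8 higher and 13 lower in NIL-Gn1, or 7.84% of tested loci against 2.12% elsewhere (odds ratio 3.93, exact p = 8.75e-07). At R5 it was 3 of 26 calls (odds ratio 3.50, exact p = 0.066) and at R4 1 of 11 (2.67, exact p = 0.334). Most calls lay elsewhere: over R1 and R2 chromosome 12, which carries LOC_Os12g39970, had 17 calls among 412 tested loci, against 34 among 1012 on chromosome 1. The locus next to OsCKX2 among those, LOC_Os01g10140, was lower (log2 fold change -1.31, SE 0.190, adjusted p = 3.22e-07). For calls between tissues the odds ratios were 1.42 (exact p = 0.117) for R4 against R2 in Koshihikari and 1.52 (exact p = 0.228) for R5 against R2 in NIL-Gn1. With calls at an adjusted p under 0.1 the first was 1.67 (exact p = 0.00586), and that between cultivars at R5 3.85 (4 of 32 calls, exact p = 0.0272).

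**Figure D1:**
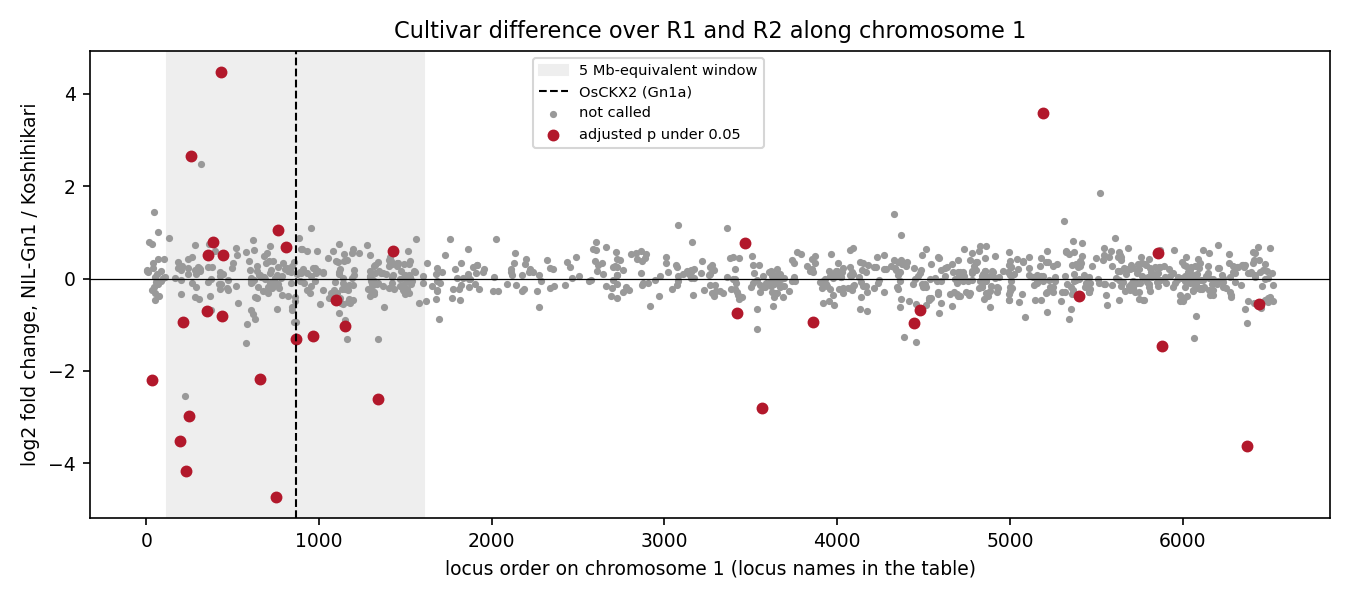
Log2 fold change of NIL-Gn1 over Koshihikari, averaged over R1 and R2 (vertical axis), for the 1012 tested loci of chromosome 1 in the order of their names (horizontal axis); red points are the 34 called loci, the dashed line is OsCKX2 and the grey band the window of 744 loci on each side. Of the 34 red points, 21 lie in the band, both above and below 0.

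In R5 tissue the named difference was TAW1 (LOC_Os10g33780), an ALOG-family regulator that holds meristems in the branching phase. TAW1 was 3.21-fold higher in NIL-Gn1, at 489 ± 84.2 CPM (SD, n = 2) against 146 ± 61.9 CPM (n = 3; log2 fold change 1.68, SE 0.287, adjusted p = 0.000135), a call kept in every setting tried. In total 26 loci were called, 18 higher and 8 lower, among them LOC_Os06g46030 (2.86, SE 0.495, 0.000135), LOC_Os12g39970 (2.04, SE 0.358, 0.000183) and LOC_Os01g05610 (-1.72, SE 0.334, 0.00141). LOC_Os01g03020 had 2 UMIs in NIL-Gn1 against 63 in Koshihikari, a ratio of 23.4 (95% counting interval 6.22 to 198; adjusted p = 0.000111). Of the 10 branch and spikelet regulators 1 was higher and 9 were not called; OsCKX3 passed only adjusted over the list alone (2.95, SE 1.19, adjusted p = 0.344 over all loci). The count rested on few libraries: it was 4 without NIL-Gn1 R5 replicate 1, 16 without NIL-Gn1 R5 replicate 2, 13 without Koshihikari R5 replicate 3 and 10 without Koshihikari R5 replicate 5. Without NIL-Gn1 R5 replicate 1 these loci lost their calls: LOC_Os06g46030 (adjusted p = 0.291), LOC_Os12g39970 (0.0526), LOC_Os01g05610 (0.297) and LOC_Os01g03020 (0.179).

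At R4 NIL-Gn1 had 1 library, assumed to vary like the other groups, so that each SE and p rests on their spread. TAW1 was at 442 CPM in NIL-Gn1 and 167 ± 107 CPM (SD, n = 3) in Koshihikari (log2 fold change 1.41, SE 0.314, adjusted p = 0.0165). That call was lost without Koshihikari R4 replicate 2 (1.27, adjusted p = 0.207) or replicate 3 (1.08, 0.321) and with the replicate number as a block (1.45, 0.0684), and the total of 11 calls, 8 higher and 3 lower, was 4 without any of the Koshihikari R4 libraries. OsGA2ox1 passed higher only adjusted over the list alone. LOC_Os12g39970 was higher in that library as well (3.70, SE 0.451, adjusted p = 3.9e-09), and LOC_Os01g03020 had 3 UMIs in NIL-Gn1 against 57 in Koshihikari, a ratio of 16.6 (95% counting interval 5.41 to 83.1; adjusted p = 0.000963). This call was lost with the replicate number as a block (adjusted p = 0.0684) and with limma-voom (0.0997). LOC_Os05g01060 was higher (1.69, SE 0.326, adjusted p = 0.00193), a call lost without Koshihikari R4 replicate 3 (0.0657), and LOC_Os09g07570 lower (-2.66, SE 0.564, 0.00999), a call lost without Koshihikari R4 replicate 4 (0.229), with no filter (0.0501), with the block (0.0676) and with limma-voom (0.0697).

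R2 was set against R1 within each line. In Koshihikari edgeR called 0 loci (439 at an unadjusted p under 0.05, smallest adjusted p 0.635), and DESeq2 and limma-voom called 0 and 0. OsMADS18 (log2 fold change 0.00, SE 0.186), TAW1 (-0.07, SE 0.155) and OSH1, the KNOX gene of the shoot meristem (-0.21, SE 0.261), were not distinguishable. On counts simulated for this comparison 76 of 100 loci changed 4-fold and 24 of 100 changed 2-fold were recovered. In NIL-Gn1 6 loci were called, 1 higher and 5 lower, with no list gene among them. LOC_Os09g07570 was higher at R2 (1.17, SE 0.251, adjusted p = 0.0151), a call lost without NIL-Gn1 R1 replicate 1 (0.0603), replicate 2 (0.0527) or replicate 4 (0.0524) and in a fit of only the groups compared (0.0834). LOC_Os07g12340 was lower (-2.68, SE 0.525, 0.0043), and LOC_Os04g23550 had 2 UMIs at R2 against 83 at R1, a ratio of 40.8 (95% counting interval 10.9 to 342; adjusted p = 0.0043). Of the 83 UMIs 59 came from NIL-Gn1 R1 replicate 4, without which the ratio was 14.1 (3.51 to 123) and the locus did not pass the filter on low counts; with limma-voom its call was lost (-3.02, adjusted p = 0.0735). The count was 0 without NIL-Gn1 R1 replicate 4 and 22 without NIL-Gn1 R1 replicate 8, and scaling by the upper quartile gave 2 higher and 5 lower. The interaction of cultivar with R2 against R1 gave 0 calls by edgeR (446 at an unadjusted p under 0.05, smallest adjusted p 0.181), 0 by DESeq2 and 0 by limma-voom. DST passed it only adjusted over the list alone (log2 difference -1.07, SE 0.304, adjusted p = 0.419 over all loci).

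Between R2 and R4 tissue of Koshihikari, TAW1 fell 5.37-fold, from 888 ± 148 CPM (SD, n = 5) to 167 ± 107 CPM (n = 3; log2 fold change -2.42, SE 0.236, adjusted p = 1.76e-14). DEP1, a G-protein gamma subunit gene that sets panicle density, rose from 81.2 ± 6.30 to 202 ± 61.7 CPM (1.33, SE 0.370, 0.0153). OsGA2ox1, which encodes a gibberellin-inactivating enzyme, went from 27 UMIs to 1 UMI, a ratio of 15.6 (95% counting interval 2.56 to 637; adjusted p = 0.0303). In total 444 loci were called, 255 higher and 189 lower (213 and 233 with upper quartile scaling, which turns the majority), led by LOC_Os03g47940 (3.33, SE 0.344, 4.48e-13) and LOC_Os03g53950 (3.12, SE 0.401, 5.3e-09) upward and by LOC_Os05g01060 (-1.68, SE 0.259, 1.53e-06) and LOC_Os05g45430 (-1.83, SE 0.314, 4.86e-05) downward. Each of these 4 loci kept its call in every setting tried, as did TAW1. The DEP1 call was lost without Koshihikari R4 replicate 2 (adjusted p = 0.114) or replicate 4 (0.0661) and with Koshihikari R2 reduced to replicates 2 and 3 (0.0596). The OsGA2ox1 call was lost with limma-voom (0.114) and without Koshihikari R2 replicate 2 (0.0546) or replicate 3 (0.127), or Koshihikari R4 replicate 2 (0.129) or replicate 3 (0.143). Without Koshihikari R2 replicate 3 the OsGA2ox1 ratio was 9.97 (1.45 to 429). The count itself was 253, 201 and 280 without Koshihikari R4 replicate 2, 3 and 4.

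By gene group, 1 of 10 branch and spikelet regulators rose between R2 and R4 (DEP1), 1 fell (TAW1) and 8 were not called. Of the 8 meristem maintenance genes 1 rose, FON1, a receptor kinase of the CLAVATA pathway, from 3 UMIs to 16 UMIs (ratio 9.26, 95% counting interval 2.65 to 49.6; adjusted p = 0.0466). FON1 ranged from 0 to 123 CPM within R4, its ratio was 3.56 (0.602 to 24.3) without Koshihikari R4 replicate 3, and it lost its call in 8 of 14 fits, among them without Koshihikari R2 replicate 1 (0.0910), replicate 2 (0.0528) or replicate 3 (0.139) and without Koshihikari R4 replicate 2 (0.0730). Adjusted over the list alone the KNOX genes OSH6 (-1.01, SE 0.392) and OSH15 (-1.05, SE 0.393) also passed, lower, as did the floral transition genes OsMADS14 (1.67, SE 0.553) and OsMADS34 (2.40, SE 0.897), higher. The lateral organ marker OsYABBY5 (0.61, SE 0.222) and the heat shock genes HSP70 (0.51, SE 0.223) and HSP101 (-2.29, SE 1.13) passed in the same way. Of the 4 photosynthesis markers 1 rose, CAB1R, a chlorophyll-binding protein whose reads can be shared with near-identical family members (212 ± 79.6 to 616 ± 283 CPM; 1.47, SE 0.433, adjusted p = 0.0411). CAB1R lost its call in 10 of 18 fits, with adjusted p up to 0.265, reached without Koshihikari R4 replicate 4. The calls without Koshihikari R4 replicate 3 (0.0712) and Koshihikari R2 replicate 1 (0.0528), 2 (0.0776), 4 (0.0712) and 5 (0.0552) were lost too. None of the 6 cell division genes was called, over all loci or adjusted over the list alone.

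Between R4 and R5 of Koshihikari edgeR called 0 loci (536 at an unadjusted p under 0.05, smallest adjusted p 0.0569), and DESeq2 and limma-voom called 1 and 1. TAW1 was at 167 ± 107 CPM at R4 and 146 ± 61.9 CPM at R5 (log2 fold change -0.16, SE 0.311), and OsMADS15, a relative of OsMADS18, at 495 ± 93.4 and 826 ± 62.1 CPM (0.73, SE 0.600, adjusted p = 0.868). OsCKX3 passed, lower, only adjusted over the list alone. The count was 1 without Koshihikari R4 replicate 2 and 2 without Koshihikari R5 replicate 5. On simulated counts 56 of 100 loci changed 4-fold were recovered in this design.

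In NIL-Gn1, R5 was set against R2. OsGA20ox1 rose 2.19-fold, from 171 ± 41.9 CPM (SD, n = 8) to 369 ± 69.0 CPM (n = 2; log2 fold change 1.13, SE 0.274, adjusted p = 0.00552). In total 187 loci were called, 159 higher and 28 lower, led by LOC_Os03g47940 (3.50, SE 0.279, 1.72e-19) and LOC_Os01g15320 (5.23, SE 0.504, 2.07e-14) upward and by LOC_Os04g43580 (-2.83, SE 0.580, 0.00243) and LOC_Os02g07030 (-1.16, SE 0.268, 0.00291) downward. Without NIL-Gn1 R5 replicate 1 only 15 loci were called, and OsGA20ox1 (0.88, adjusted p = 0.625), LOC_Os04g43580 (0.351; also 0.0784 with limma-voom) and LOC_Os02g07030 (0.349) lost their calls. Of the 3 gibberellin genes 1 rose and 2 were not called; TAW1 was not called (-0.69, SE 0.216, adjusted p = 0.0693). TAW1, SNB, OSH71 and OsGA2ox1 passed, lower, and OsMADS34 and OsYABBY5, higher, only adjusted over the list alone. The calls shared 72 higher loci with the 255 of Koshihikari R4 against R2, where independent lists would share 5.47, and 10 lower loci where 0.715 would be shared.

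R4 and R5 were then pooled against R1 and R2 within each line, a contrast chosen after the data were seen. In Koshihikari the branching regulator TAW1 fell 5.80-fold (log2 fold change -2.54, SE 0.166, adjusted p = 1.41e-26). SNB, an AP2-type gene that times the spikelet transition, fell by 1.28 (SE 0.259, 8.91e-05) on the log2 scale. The MADS-box genes OsMADS34 (2.31, SE 0.593, 0.00258), OsMADS15 (1.84, SE 0.420, 0.00259) and OsMADS14 (1.43, SE 0.363, 0.00617), which specify inflorescence and spikelet meristems, rose together, while OsFD1, the bZIP partner of florigen, fell by 1.13 (SE 0.309, 0.0105). In NIL-Gn1 the same 3 MADS-box genes rose (2.81, SE 0.634, 0.0013 for OsMADS34; 1.70, SE 0.472, 0.0357 for OsMADS15; 1.39, SE 0.408, 0.0494 for OsMADS14), OsMADS18 rose by 0.61 (SE 0.171, 0.0218) and TAW1 fell 1.74-fold (-0.80, SE 0.172, 0.000589). In total 1220 loci were called in Koshihikari (657 higher, 563 lower; 590 and 638 with upper quartile scaling, which turns the majority) and 291 in NIL-Gn1 (214 higher, 77 lower); 161 higher and 34 lower loci were shared, where independent lists would share 19.0 and 5.85.

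The gene groups moved as follows. Among 7 florigen and floral transition genes 3 rose and 1 fell in Koshihikari, and 4 rose in NIL-Gn1; adjusted over the list alone 5 passed in each line. Among 10 branch and spikelet regulators 2 rose (DEP1, DST) and 2 fell (TAW1, SNB) in Koshihikari and 1 fell (TAW1) in NIL-Gn1; adjusted over the list alone 6 and 2 passed. Of the 8 meristem maintenance genes the KNOX genes OSH15 (-0.94, SE 0.276, adjusted p = 0.00979) and OSH6 (-0.73, SE 0.254, 0.0342) fell in Koshihikari, and OSH71 (-1.15, SE 0.353, 0.0407) fell in NIL-Gn1; adjusted over the list alone SH5, a BELL-type homeobox gene, also passed in Koshihikari, higher (0.66, SE 0.275, adjusted p = 0.0858 over all loci). The cytokinin oxidase OsCKX3 fell by 2.23 (SE 0.576, 0.00272) and OsGA2ox1 went from 62 UMIs to 3 UMIs in Koshihikari (ratio 11.0, 95% counting interval 3.58 to 54.6; adjusted p = 0.00036). The OsCKX3 value rests largely on R5, with 1 UMI in 3 libraries. At R4 OsCKX3 was at 29.0 ± 34.0 CPM (8 UMIs), against 46.0 CPM at R1 and 56.8 CPM at R2, and it was not called between R2 and R4. DL, a YABBY gene of the carpel and midrib, fell by 0.95 (SE 0.339, 0.0486). Of 4 photosynthesis markers, taken as signs of other cell types, 3 rose in Koshihikari: CAB1R (1.83, SE 0.296, 5.19e-05), CAB2R (2.22, SE 0.445, 0.000701) and PsbO (2.38, SE 0.683, 0.00786), each of a gene family whose reads can be shared between copies; 0 of 4 were called in NIL-Gn1 by edgeR. The lateral organ marker OsYABBY5 rose in both lines (0.94, SE 0.152, 6.68e-07; 0.62, SE 0.176, 0.0213), and HSP70 rose in Koshihikari (0.42, SE 0.156, 0.0478). None of the 6 cell division genes and neither of the 2 measured cytokinin response genes was called in either line; CYCB2;2, a B-type cyclin (-0.78, SE 0.281, adjusted p = 0.109 over all loci), and OsGA2ox1 passed, lower, in NIL-Gn1 only adjusted over the list alone.

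**Figure D2:**
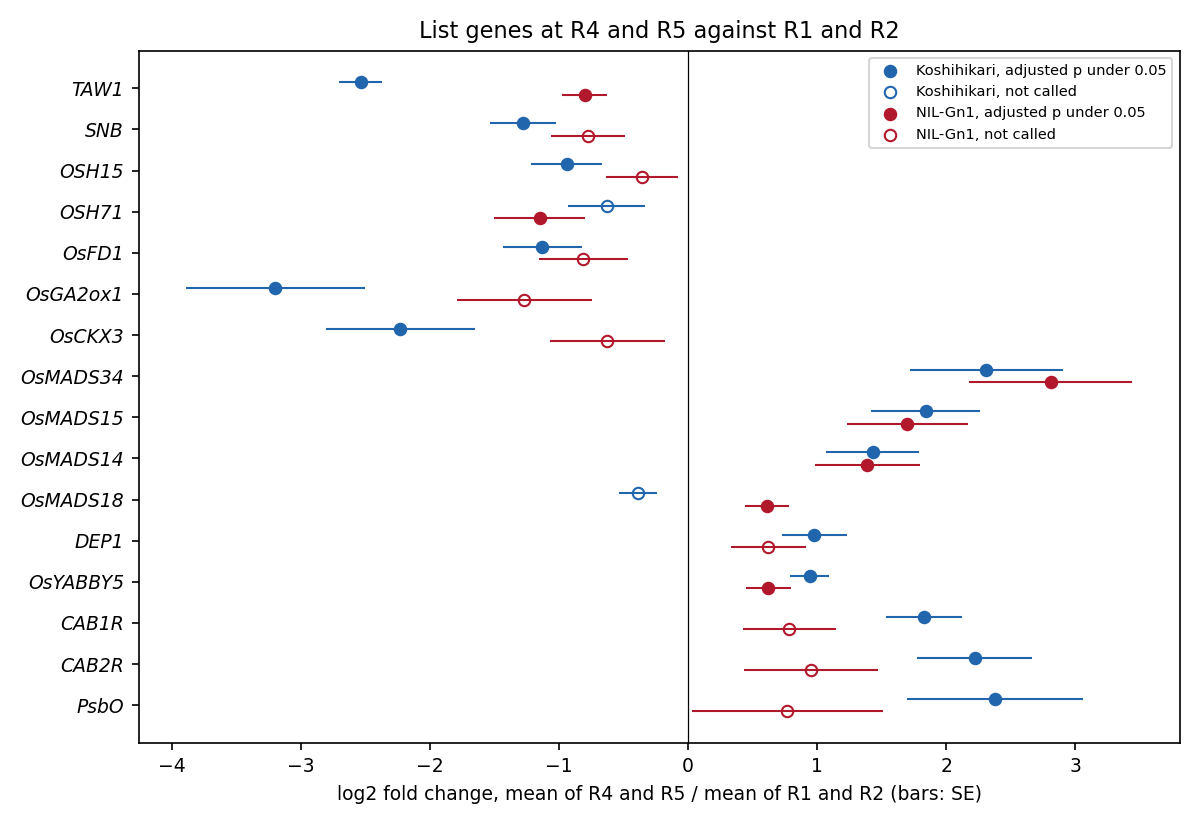
Log2 fold change of the mean of R4 and R5 over the mean of R1 and R2 (horizontal axis) for list genes (vertical axis) in Koshihikari (blue) and NIL-Gn1 (red), with bars of 1 SE; filled points had an adjusted p under 0.05. TAW1 lies at -2.54 in Koshihikari and -0.80 in NIL-Gn1, while OsMADS34, OsMADS15 and OsMADS14 lie to the right of 0 in both.

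Several NIL-Gn1 calls of this contrast were lost when 1 of the few R5 libraries was left out, most with little change in fold. Without NIL-Gn1 R5 replicate 1 the count was 92, and TAW1 (-0.71, adjusted p = 0.0532), OsMADS34 (2.53, 0.270), OsMADS15 (1.64, 0.291), OsMADS14 (0.82, 0.680) and OSH71 (-1.11, 0.298) were not called. Without NIL-Gn1 R5 replicate 2 OsMADS18 (0.46, 0.178), OsYABBY5 (0.48, 0.177), OsMADS15 (1.74, 0.0615) and OSH71 (-1.17, 0.0719) were not called. The NIL-Gn1 calls of OsMADS14 and OSH71 were also lost in most or many other settings, in 16 and 9 of 27 fits in all. OsMADS15 also lost its call with no filter (0.0677), with DESeq2 (0.121) and in a fit of only the groups compared (0.0886), and OsMADS18 with DESeq2 (0.0571). In Koshihikari PsbO lost its call without Koshihikari R4 replicate 4 (1.75, 0.180), and OsFD1 with Koshihikari R2 reduced to replicates 2 and 3 (-0.98, 0.0540).

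The difference between the lines in this shift was tested as an interaction. The single NIL-Gn1 R4 library, which weighs as much here as the NIL-Gn1 R5 group, could not be left out. The fall of TAW1 was smaller in NIL-Gn1 by 1.73 on the log2 scale (SE 0.234, adjusted p = 1.32e-07), a call kept in every setting tried, with values from 1.56 to 2.05. OsMADS18 also differed, by 0.996 (SE 0.229, adjusted p = 0.0153), since it rose in NIL-Gn1 and was at -0.39 (SE 0.151, adjusted p = 0.0651) in Koshihikari. Its call was lost without Koshihikari R5 replicate 2 (0.0607) or NIL-Gn1 R5 replicate 2 (0.0985). In total 23 loci were called, 16 higher and 7 lower, and 35 without Koshihikari R2 replicate 5. Among them were LOC_Os05g01060 (1.59, SE 0.245, 7.28e-06), LOC_Os06g46030 (1.99, SE 0.348, 0.000137), LOC_Os02g46420 (-4.32, SE 0.745, 0.000126) and LOC_Os02g42412 (-3.31, SE 0.672, 0.00238). In NIL-Gn1 LOC_Os02g46420 rested on 6 UMIs at R4 and 1 UMI at R5, and LOC_Os02g42412 on 4 and 3 UMIs. OsMADS34 (0.50, SE 0.835, adjusted p = 0.851), OsMADS15 (-0.14, SE 0.663, 0.963), OsMADS14 (-0.04, SE 0.603, 0.992) and CAB1R (-1.04, SE 0.480, 0.354) were not called, and DL passed only adjusted over the list alone.

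**Figure D3:**
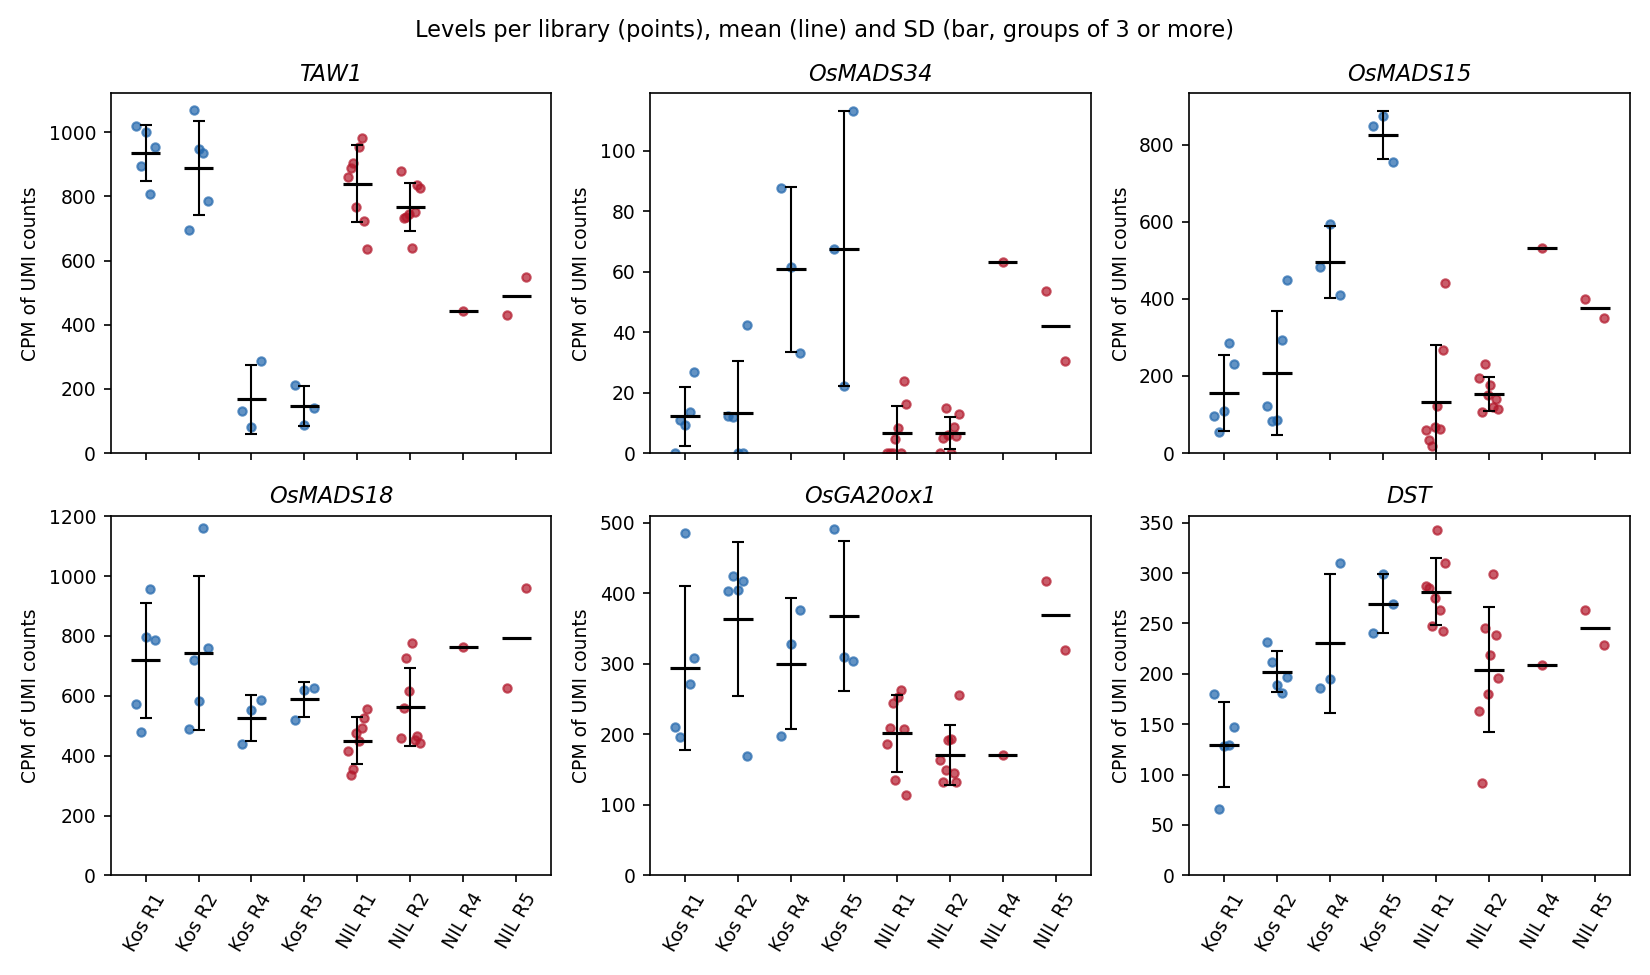
Level in CPM of UMI counts (vertical axis) of TAW1, OsMADS34, OsMADS15, OsMADS18, OsGA20ox1 and DST in each library (points) by line and tissue code (horizontal axis), with the mean (line) and SD (bar, groups of 3 or more). TAW1 lies between 637 and 1070 CPM in all R1 and R2 libraries, between 82.0 and 288 CPM in Koshihikari R4 and R5 and between 430 and 549 CPM in NIL-Gn1 R4 and R5.

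The 4 lists with 6 or more measured genes were also tested as sets by camera with a preset correlation. In R5 against R2 of NIL-Gn1 the cell division list (median log2 fold change -0.51, adjusted p = 0.0404) and the meristem maintenance list (-0.52, adjusted p = 0.0404) were lower, and neither call was kept (adjusted p = 0.325 and 0.248 with an estimated correlation). The floral transition list was higher at R4 and R5 in NIL-Gn1 (median 0.61, adjusted p = 0.0386; adjusted p = 0.343 with an estimated correlation). In the interaction of line with this shift the cell division list was lower (median -0.48, adjusted p = 0.0497; adjusted p = 0.367 with an estimated correlation). The branch and spikelet list in Koshihikari was not called by camera for R4 and R5 (adjusted p = 0.469), while fry, which asks whether genes of a set move at all, gave adjusted p = 0.0148 for a net fall and 3.74e-08 for changes in either direction. For the floral transition list the median and mean differed in sign between cultivars at R2 (0.12 and -0.09) and R5 (0.01 and -0.16), where camera called no list (smallest adjusted p = 0.0888 and 0.318). In R4 against R2 of Koshihikari the same held for the floral transition list (-0.07 and 0.57), the meristem list (-0.48 and 0.04) and the branch list (0.06 and -0.06). Signs also differed for the branch list in R2 against R1 of Koshihikari (-0.03 and 0.10) and at R4 and R5 of NIL-Gn1 (0.03 and -0.02), for the meristem list in R5 against R4 of Koshihikari (0.11 and -0.04) and for the floral transition list in the interaction of line with the R4 and R5 shift (-0.03 and 0.18). In R2 against R1 of Koshihikari camera gave the floral transition list an upward sign while its median and mean were -0.06 and -0.07.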

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

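The tests of placement, of lost donor reads, of mixing, of low depth and of Koshihikari R2 replicate 1 were chosen after the result was seen, as were the contrasts that pool R4 with R5 or R1 with R2. Those of mixing, of low depth and of Koshihikari R2 replicate 1 replaced earlier tests that could not tell the explanations apart.

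TAW1, the regulator that holds meristems in branching, and OsMADS18, a floral transition gene, shifted differently between the lines from R1 and R2 to R4 and R5, by 1.73 and 0.996 on the log2 scale. The same difference was 1.59 for LOC_Os05g01060, 1.99 for LOC_Os06g46030, -4.32 for LOC_Os02g46420 and -3.31 for LOC_Os02g42412. For LOC_Os02g46420 and LOC_Os02g42412 it rested on few UMIs in NIL-Gn1 R4 and R5.

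Calls between lines at R1 and R2 were enriched around Gn1, though most lay elsewhere. Even placement of calls along the genome was argued against by Fisher's exact test (p = 8.75e-07 over R1 and R2), and at R5 the answer turned on the threshold for calls (p = 0.066, and 0.0272 with calls at an adjusted p under 0.1); it was not excluded at R4 (p = 0.334). Reads lost from donor alleles in alignment, where they are not counted at another locus, would only lower counts in NIL-Gn1. Of the 21 calls in the window 8 were higher in it. Whether donor reads were counted at another locus was not tested. For the 13 lower calls lost reads stay open: for 2 of them the cultivar difference changed between R1 and R2 and R4 and R5, as lost reads alone would not give, and the other 11 cannot be told apart from donor sequence variants. Carried donor segments with other cis-regulation are also open and were not tested.

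The shift to R4 and R5 was smaller in NIL-Gn1 on the first component and in medians over gene sets. In R5 against R1 the median log2 fold change of the rising genes described next was 1.21 in Koshihikari and 0.897 in NIL-Gn1. That of the falling genes was -0.833 and -0.509. For single genes the shift was called different at 23 of 7406 loci, where chance is not excluded. If tissue like R1 and R2 was mixed into the NIL-Gn1 R5 libraries, rising and falling genes, chosen from R4 against R2 averaged over both lines and measured in R5 against R1, should give a like share. They gave 34.2% (95% interval over genes 19.9 to 49.5, 252 genes) and 32.3% (22.4 to 42.6, 159 genes), and 28.8 to 55.6% with either NIL-Gn1 R5 library left out, so mixing may account for part of it, though less advanced tissue would give the same values (genes chosen in Koshihikari alone, which favours a smaller shift in the other line, gave 52.2% and 43.8%). A mixture would give means in NIL-Gn1 R5 between that of its R1 and R2 and that of Koshihikari R5. Of the 23 loci whose shift was called between the lines, 6 had such a mean. Among them were TAW1 (489 CPM between 804 and 146 CPM) and LOC_Os06g46030 (182 between 297 and 26.3 CPM). The other 17 had a mean outside, among them OsMADS18 (793 CPM against 506 and 588 CPM) and LOC_Os02g46420 (2.98 CPM, 1 UMI, against 31.0 and 146 CPM). Some lay outside by little, such as LOC_Os04g40040 (289 CPM against 179 and 278 CPM). These loci were chosen by the line difference in these same libraries, so the split of 6 and 17 cannot weigh for or against mixing. The low depth of NIL-Gn1 R5 replicate 2 as the whole cause was argued against, since the other R4 and R5 libraries of NIL-Gn1 scored at most 23.5 on the first component, under the lowest of Koshihikari (32.2). A line difference in development stays open and untested, and the labels do not define the tissue codes. Other tissue in the Koshihikari R4 and R5 libraries was not tested either. Of 4 photosynthesis markers, taken as signs of other cell types, 3 rose there. In the interaction with line 0 of the 4 were called.

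Koshihikari R2 replicate 1 stood apart on the second component, as replicates 4 and 5 did on the fourth. Without replicate 1, 15 of the 37 cultivar calls at R2 stayed, while 24 or more stayed without any other library of these groups. Of the 22 lost calls 4 also lost most of their log2 fold change, against 0 without any other library, and the 22 kept a median of 90.8% of it. It is therefore not shown that 1 library standing apart makes most of the calls, and how far it did stays open. What sets it apart was not tested, and no biological explanation was tested.

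Chance assignment of libraries was tested by other splits of the same libraries. The counts between lines at R4 (11) and R5 (26) and for R5 against R2 in NIL-Gn1 (187) were not tested in this way. There were 100 splits, the real one included, except where another number is given. No other split reached the count between lines at R1 (50, highest other 25), R2 (37, 12) or R1 and R2 together (172, 2). The same held for R4 and R5 in Koshihikari (1220, 191) and NIL-Gn1 (291, 140). It also held for R4 against R2 in Koshihikari (444, highest other 156 among 56 splits). This argues against chance assignment in these comparisons, within the few splits drawn. The splits do not allow for the choice of the pooled contrasts after the data were seen. For R2 against R1 in NIL-Gn1 (6, 4) the margin is narrow and chance is not excluded. There the edgeR count was 0 without NIL-Gn1 R1 replicate 4 and in a fit of only the groups compared. With all libraries 555 loci had an unadjusted p under 0.05, with 6 calls by DESeq2 and 6 by limma-voom. Nor is chance excluded for the interaction of line with the R4 and R5 shift (23, 21), which fell to 19 with 1 library left out. For R2 against R1 in Koshihikari (highest other 0) and the interaction of line with R2 against R1 (highest other 20) the real count was 0 by edgeR, with 439 and 446 loci at an unadjusted p under 0.05 and 0 calls by DESeq2 and limma-voom. All 100 splits reach a count of 0, so they say nothing on chance there. For R5 against R4 in Koshihikari the 10 splits are too few (real 0, highest other 0).

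Single libraries stood far from the rest of their group in 16 of 172 checks, by a ratio of the gap to the range of the group. Chance alone gives 8.6 if levels are normal, which counts near 0 are not. Only the R1 and R2 groups were checked, since those of R4 and R5 had too few libraries. The library total of Koshihikari R2 replicate 3 was 209653 UMIs, the highest of 5 (ratio 0.828). In Koshihikari R1 the ratio was 0.829 for LOC_Os01g10140 (replicate 2, lowest), 0.76 for LOC_Os05g45430 (replicate 1, lowest), 1 for LOC_Os10g05970 (replicate 5, highest) and 0.799 for OSH71 (replicate 1, lowest). In Koshihikari R2 it was 0.942 for OsGA20ox1 (replicate 5, lowest), 0.834 for LOC_Os01g05610 (replicate 1, lowest), 0.732 for LOC_Os09g07570 (replicate 4, lowest) and 0.825 for DEP1 (replicate 3, lowest). In NIL-Gn1 R1 it was 0.529 for LOC_Os04g23550 (replicate 4, highest), 0.547 for LOC_Os01g15320 (replicate 6, highest), 0.626 for LOC_Os04g43580 (replicate 8, lowest), 0.587 for CAB2R (replicate 5, highest) and 0.601 for LOC_Os10g05970 (replicate 2, highest). In NIL-Gn1 R2 it was 1 for LOC_Os04g23550 (replicate 4, highest) and 0.556 for LOC_Os03g47940 (replicate 7, highest). A ratio of 1 arises wherever all other libraries are at 0, and these were 1 UMI of LOC_Os10g05970 and 2 UMIs of LOC_Os04g23550.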

How the results depend on the processing

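The reduction of Koshihikari R2 and the windows in loci were chosen after the data were seen. Of 80 results of named genes under the alternatives 50 kept their call in every one that gave a value and 30 lost it at least once; of 1871 values 1765 kept the call, 106 lost it and 0 turned direction. The counts of calls moved as follows, and the cause was not tested except where libraries or loci were left out. With no filter there were 17 calls between lines at R5, 28 for R2 against R1 in NIL-Gn1, 2 for R5 against R4 in Koshihikari and 45 for the interaction of line with the R4 and R5 shift. With a mean of at least 10 counts there were 1 for R2 against R1 in NIL-Gn1, 1 for R5 against R4, 100 for R5 against R2 in NIL-Gn1 and 191 for R4 and R5 in NIL-Gn1. RLE gave 1 for R5 against R4. DESeq2 gave 5 at R4 and 1 for R5 against R4, and limma-voom 124 at R1, 24 at R2, 15 at R5, 5 at R4 and 1 for R5 against R4. A fit of only the groups compared gave 15 at R2, 0 for R2 against R1 in NIL-Gn1 by edgeR, where the fit of all libraries had 555 at an unadjusted p under 0.05 and DESeq2 and limma-voom called 6 and 6, 217 for R4 against R2 in Koshihikari and 4 for R5 against R4. With replicate numbers as a block there were 15 at R2, 10 at R5, 5 at R4, 10 for R2 against R1 in NIL-Gn1 and 110 over R1 and R2. Deviations of same-number libraries from their group means correlated at 0.079 or below, with 0 pairs over 0.1. Libraries of unlike number were not compared, so whether the numbers pair the libraries stays open. Koshihikari R2 reduced to replicates 2 and 3 gave 228 for R4 against R2, 38 for the interaction and 100 over R1 and R2. Of 2 list calls in the planned comparisons 0 were kept with an estimated correlation and 0 with fry. The R2 odds ratio near Gn1 was 3.39 (exact p = 0.127) in the narrower window.

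Leaving out 1 library gave 34 to 60 calls at R1, 16 to 44 at R2 (16 without Koshihikari R2 replicate 1), 118 to 178 over R1 and R2, and 4 to 4 at R4, each without 1 of Koshihikari R4 replicates 2, 3 and 4. At R5 it gave 4 to 20 (4 without NIL-Gn1 R5 replicate 1, 16 without 2, 13 without Koshihikari R5 replicate 3, 10 without 5). R2 against R1 gave 0 to 0 in Koshihikari and 0 to 22 in NIL-Gn1 (0 without NIL-Gn1 R1 replicate 4, 22 without 8), and their interaction 0 to 0. R4 against R2 gave 201 to 429 (253, 201 and 280 without Koshihikari R4 replicates 2, 3 and 4), R5 against R4 0 to 2 (1 without Koshihikari R4 replicate 2, 2 without Koshihikari R5 replicate 5), and R5 against R2 in NIL-Gn1 15 to 188 (15 without NIL-Gn1 R5 replicate 1). R4 and R5 gave 1028 to 1250 in Koshihikari, 92 to 303 in NIL-Gn1 (92 without NIL-Gn1 R5 replicate 1) and 19 to 35 in the interaction (35 without Koshihikari R2 replicate 5). The OsCKX2 difference of mean CPM was -2.29 to 0 at R1 and -1.08 to 1.05 at R2. Not run were the lists by product name, as no product names could be joined; the planned fit without libraries of far lower total than the median had 0 libraries to leave out. Depth limits OsCKX2 and other genes near 0 UMIs. Between lines at R4 and R5, with 1 and 2 NIL-Gn1 libraries, 3 and 4 of 100 simulated 2-fold changes were recovered.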

Other observations

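Cytokinin response was read from 2 measured genes. OsRR2, a type-A response regulator that cytokinin induces, was at 99.6 ± 29.6 CPM (SD, n = 5) in Koshihikari R1 and 102 ± 34.5 CPM (n = 8) in NIL-Gn1 R1, and at 88.5 ± 41.7 and 118 ± 33.8 CPM at R2. OsRR1 was at 33.5 ± 12.2 and 29.9 ± 12.9 CPM at R1. Neither was called between lines by edgeR, so a difference in cytokinin response was not detectable by these genes at this depth. The replication gene PCNA was at 387, 327, 376 and 358 CPM (means) at R1, R2, R4 and R5 of Koshihikari and at 378, 348, 360 and 292 CPM in NIL-Gn1. The mitotic kinase CDKB2;1 was at 327, 241, 349 and 275 CPM and at 293, 291, 257 and 179 CPM. Neither was called in any comparison.

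Counts of OsMADS1 and LAX1, picked after their values were seen, were low. OsMADS1, a SEPALLATA-like gene of the spikelet, had 5 UMIs in Koshihikari R5 (15.9 ± 4.29 CPM, n = 3) and 2 UMIs in NIL-Gn1 R5 (10.6 ± 6.56 CPM, n = 2), 1 UMI in NIL-Gn1 R1 (1.02 CPM over 8 libraries) and 0 UMIs in Koshihikari R1, R2 and R4 and in NIL-Gn1 R2 and R4. LAX1, a regulator of axillary meristems, was at 5.40, 5.60, 24.6 and 20.1 CPM (means) at R1, R2, R4 and R5 of Koshihikari and at 8.04, 7.79, 3.95 (1 UMI) and 11.9 CPM in NIL-Gn1. These genes did not pass the filter on low counts and were not tested.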
